A study of Rattus norvegicus with 6 samples.

How the data were processed

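Total RNA of 6 cultures of neonatal rat ventricular myocytes, 3 per group, was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays of design 028282, 1 array per culture, per the labels' protocols and the file headers. The authors scanned and quantified the arrays with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The deposited scanner files give each spot's intensity on a linear scale, background-subtracted and detrended within its array and not normalized between arrays, per the file headers. They also give the raw median intensity of spot and background and flags of other kinds, such as well above background. The deposited series table holds log2 values, whose scale and centring are not given in the sources used here. Set against the scanner intensities, the columns correlated at 0.995 to 0.9995 across probes and had the same median, 6.51, in all 6 columns, as quantile normalization gives. It was used as an alternative only.

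Groups and replicate numbers came from the sample titles. Slides were inferred from the scan identifiers in the file headers. Each sample is described as an independent experiment, without saying which cultures shared a litter, so p-values measure the spread between these samples. Fibroblasts were reduced by preplating and bromodeoxyuridine was added to the medium, per the labels' protocols. Spots flagged as non-uniform or population outliers, 322 to 594 of 42877 per array, and control spots were left out. The log2 processed intensity of each array was shifted by its 75th percentile, which lay between 1182 and 1381 intensity units on slide 1 and at 1718 and 1775 on slide 2, and the spots of a probe were averaged. Probes well above background on all 3 arrays of at least 1 group were kept, no spot was saturated, and 44 probes with no value on some array were dropped. The headers place the probes on build rn4. Gene names were taken from a RefSeq gene table of assembly GRCr8 by unversioned transcript accession and no coordinates were used. Of 30367 probes, 18005 matched 1 gene, 0 matched several and 12362 had no name. The brightest probe stood for a gene, and unnamed probes were tested each on its own, giving 19920 features of which 11580 were named genes. Of 103 called genes with several tested probes, 15 had probes that differed in sign.

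Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), without covariates, and p-values were adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. Log2 fold changes are si-uc.323 minus si-scramble, and errors are standard errors of the fit. For a probe not well above background on any array of one group, the fold is a bound: the brighter group's mean against the mean, per array, of the higher of the lowest signal among probes well above background and the dim probe's own. Such a bound is a point estimate and carries no sampling error. The 36 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, 2-sided and adjusted over the 36 lists, and again with an estimated correlation and with fry. The median, the mean and the camera direction of a list differed in sign for the sarcomere, p53, muscle atrophy, ribosomal protein and epicardial lists, none of them called. Named genes were chosen by a rule also fixed beforehand. It took the 10 largest increases and 10 largest decreases among called genes with non-overlapping groups, signal above background in the higher group and a proper symbol. It also took up to 4 called members of each called list (with the lowest adjusted p), the 2 members with the lowest adjusted p of any other list with a called member, and a fixed set of hypertrophy and metabolic genes. Some genes that the rule names are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

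The alternatives were normexp background correction, quantile normalization, a median shift, the series values, no background filter, a filter over all 6 arrays, the mean over probes, every probe on its own, a trended and robust prior, array weights, replicate and slide blocks and leaving out each array. After the data were seen, cyclic loess normalization and a fit of the 4 arrays of slide 1 were added. The files hold no mean spot intensity, so normexp used the median spot intensity with an offset of 50. The offset is added to each corrected intensity and pulls the log2 fold changes of dim probes towards 0. The fit was tested on simulated data for this comparison with 19920 features: of 200 changed features it recovered 1.49% at a log2 fold change of 0.5, 43.3% at 1 and 93.9% at 2. With 4000 changed features it recovered 37.2% at 0.5 and 87.3% at 1. It also called 3 unchanged features in the first of these simulations and 100 in the second. In 20 further simulations of the same fit with no changed feature, none was called. All these simulations drew independent normal noise, with the same variance in both groups and no slide difference. They therefore do not test the unequal spread of the groups, correlation between genes or the slide layout of the real arrays. A planned test of siRNA seed matches in 3 prime untranslated regions was not run, since no transcript sequences were used here, and off-target silencing by the siRNA was therefore not analysed here.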

Results

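Gene expression was measured in primary ventricular myocytes of neonatal Sprague-Dawley rats, taken at 1 to 2 days of age, after transfection with an siRNA against uc.323 (si-uc.323) or with a scrambled siRNA (si-scramble). uc.323 is a transcribed ultraconserved region, a stretch of genome that is identical in several mammals and is copied into non-coding RNA. The cells were cultured for 36 h, received 50 nmol/L siRNA for 3 h, were kept without serum for a further 21 h and were harvested 24 h after transfection. The comparison asks which genes lie downstream of uc.323 in cardiomyocyte hypertrophy, the enlargement of heart muscle cells. Each group had 3 samples, described as independent experiments, and each sample had 1 array. Of the 30367 probes of an array, 71.8% to 73.9% were well above background on the 4 arrays of slide 1 (all si-scramble arrays and si-uc.323 replicate 1), against 78.2% and 86.5% on the 2 arrays of slide 2 (si-uc.323 replicates 2 and 3), so brightness differed with slide and in part with group. The number of arrays limits the precision. The level of uc.323 was not analysed here, because no probe was matched to the region, so the knockdown itself was not checked.

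Of 11580 genes tested, 377 were higher and 334 were lower in si-uc.323 than in si-scramble at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 711 in all. Of these, 72 were higher and 63 were lower by at least 2-fold. Of 36 gene lists, camera called 8 at its preset correlation and none with an estimated correlation (lowest adjusted p = 0.101 with an estimated correlation). The lists called higher were those of the cell cycle (16 of 36 members rose), cholesterol synthesis (5 of 20) and the unfolded protein response (9 of 19). The 5 lists called lower included fatty acid oxidation (3 of 33 members fell) and adult myocyte genes (2 of 11). The estimated correlation was below the preset 0.01 for fatty acid oxidation (-0.009), adult myocyte genes (-0.017) and PPAR and PGC-1 regulators (-0.057). A higher correlation therefore does not account for the loss of those calls, and its cause was not tested. It was 0.016 for the cell cycle list, and above 0.01 in the other called lists too. In 39.1% of genes the 3 values of one group did not overlap those of the other, against 10% by chance. The split between directions depended on the scaling: 53% of the called genes were higher, against 35.6% when arrays were shifted to a common median (279 higher, 504 lower), which moved the median log2 fold change of all features from 0.04 to -0.06. The count changed when single arrays were left out, control arrays included. It was 0 without si-scramble replicate 1 (2348 genes at an unadjusted p under 0.05), 0 without si-scramble replicate 3 (2098 genes) and 13 without si-scramble replicate 2, and it was 213, 1791 and 292 without si-uc.323 replicates 1, 2 and 3. It was also 0 when probes below background were kept (3110 genes at an unadjusted p under 0.05). Among themselves the si-scramble arrays correlated at 0.9935 to 0.996 and the si-uc.323 arrays at 0.9866 to 0.9916. Leaving out a control array keeps the more variable group whole and lowers the 4 residual degrees of freedom. Lost calls therefore do not show that a call hinged on that control array, and their cause was not tested. The 711 log2 fold changes all kept their sign when any control array was left out, with a median ratio to the reported values between 0.987 and 1.0. The genes had been called on these same arrays, so kept signs are no independent check, here or in the slide fit below. All si-scramble arrays and si-uc.323 replicate 1 were on slide 1, and si-uc.323 replicates 2 and 3 were on slide 2. With the slide as a block, a fit whose contrast rests on si-uc.323 replicate 1 alone, 3 genes passed (Grp, Rec8 and Slc51a, all lower), and all 711 log2 fold changes kept their sign with a median ratio of 0.965.

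**Figure D1:**
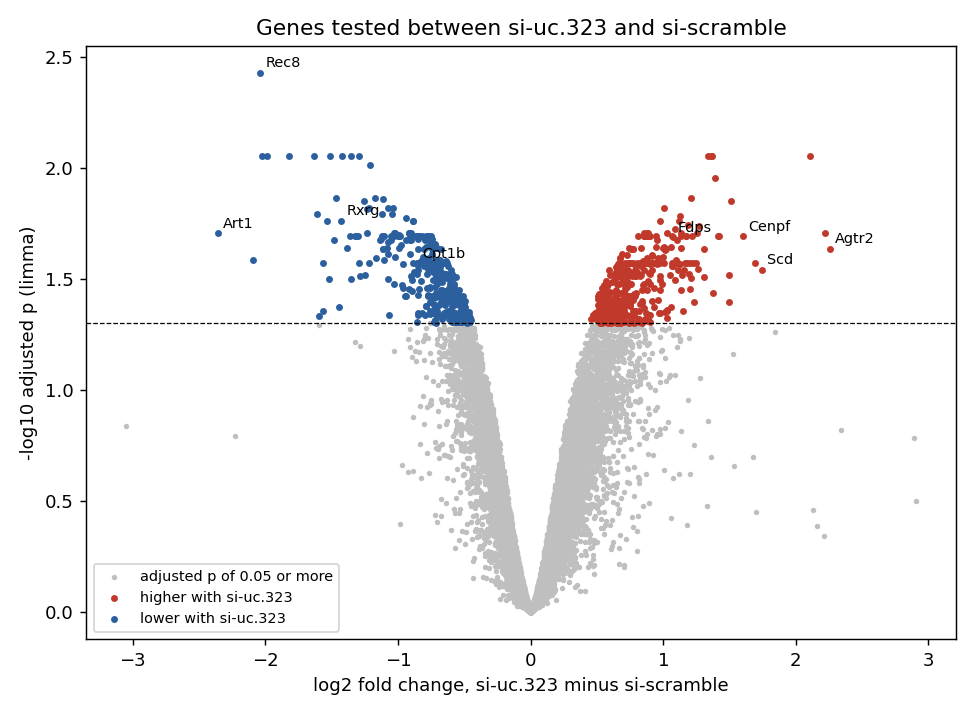
Log2 fold change (si-uc.323 minus si-scramble, x axis) against -log10 of the limma adjusted p (y axis) for each of the 11580 genes tested, 3 arrays per group. Red points are the 377 genes that were higher and blue points the 334 that were lower at an adjusted p under 0.05 (dashed line), and grey points did not pass; the fitted values of Agtr2 and Art1 are drawn although one group was not well above background.

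Among the largest increases, Agtr2, the type 2 angiotensin II receptor, was at least 1.36-fold higher with si-uc.323 (adjusted p = 0.0231) and Agmo, an ether lipid monooxygenase, at least 1.37-fold higher (adjusted p = 0.0196). Both were well above background on the 3 si-uc.323 arrays and on none of the si-scramble arrays. These bounds were not reached with normexp background correction, where Agtr2 read a log2 fold change of 0.11 (adjusted p = 0.693) and Agmo 0.08 (adjusted p = 0.734). The normexp offset pulls dim probes towards 0, so falling short there does not test a bound. Scd, a stearoyl-CoA desaturase, rose by a log2 fold change of 1.74 ± 0.29 (SE, n = 3 and 3 arrays; adjusted p = 0.0286). The mitotic genes Cenpf (1.60 ± 0.22), Nuf2 (1.51 ± 0.15) and Nek2 (1.49 ± 0.26) and the glutamate receptor subunit Gria2 (1.42 ± 0.19) followed. Nek2 was well above background on 1 of the 3 si-scramble arrays. With normexp Nek2 read 0.19 (adjusted p = 0.404) and Gria2 0.48 (adjusted p = 0.0583), neither passing, and Cenpf read 0.77 and still passed (adjusted p = 0.0335). Lilrb2 and Vom2r76 were also among the 10 largest increases. Neither was well above background on any si-scramble array, and both changed sign under normexp background correction (Lilrb2 -0.044, Vom2r76 -0.114). No fold is given for Lilrb2. For Vom2r76 the bound was 1.16-fold higher, but its direction depended on the background correction, so a rise is not established.

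Among the largest decreases, Rec8, a meiotic cohesin subunit, had the smallest adjusted p of all genes (log2 fold change -2.04 ± 0.11, adjusted p = 0.00372). Grb7, an adaptor of receptor tyrosine kinases, was lower by -1.99 ± 0.13, Grp, gastrin-releasing peptide, by -1.82 ± 0.13, and Chrng, the fetal gamma subunit of the muscle acetylcholine receptor, by -1.63 ± 0.13. Art1 was at least 2.80-fold lower, Vill at least 2.36-fold lower and Ly6d at least 2.27-fold lower, each being well above background on no si-uc.323 array. With normexp, whose offset acts here in the same way, these bounds were not reached either. The log2 fold change was -0.62 for Art1 (adjusted p = 0.0304), -0.53 for Vill (0.0583) and -0.59 for Ly6d (0.0533). Slc51a (-1.61 ± 0.17), Cx3cr1 (-1.60 ± 0.35) and Rassf2 (-1.57 ± 0.33) completed the 10 largest decreases. Rec8 (-1.17), Grp (-0.94), Chrng (-0.94) and Slc51a (-0.78) had smaller log2 fold changes with normexp and still passed. All 20 genes of the 10 largest increases and 10 largest decreases kept their direction when any array was left out. They had been chosen on the same arrays, so this is no independent check. Their adjusted p rose to between 0.0613 and 0.139 without si-scramble replicate 1 and to between 0.075 and 0.165 without si-scramble replicate 3, so that none passed, and 6 of the 20 passed without si-scramble replicate 2. Of the 20, 13 passed without si-uc.323 replicate 1 and 14 without si-uc.323 replicate 3. With the slide as a block 3 of them passed, and with normexp background correction 11 passed, with a median ratio of 0.408 to the reported log2 fold changes.

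The list of cell cycle and DNA replication genes was called higher by camera with its preset correlation (adjusted p = 9.1e-11) but not with an estimated correlation (adjusted p = 0.101 with an estimated correlation). Of its 36 measured members, 16 rose and none fell at an adjusted p under 0.05 over all features, and 24 rose adjusted over the list alone. The median log2 fold change was 0.55, and 33 members had a positive value. Besides Cenpf, the leading members were Ccnb1, the mitotic cyclin B1 (1.12 ± 0.12, adjusted p = 0.0172), Ttk, a kinase of the spindle checkpoint (1.03 ± 0.12, adjusted p = 0.0196), and Nusap1, a spindle protein (0.88 ± 0.12, adjusted p = 0.0202). The median of the list was 0.56, 0.61 and 0.62 on si-uc.323 replicates 1, 2 and 3. With the slide as a block it was 0.56. That is the replicate 1 value again and no further result, since the slide-block contrast rests on replicate 1 alone. The single-gene calls of the members named here were lost when any one of the si-scramble arrays was left out (0, 13 and 0 genes past the threshold without replicates 1, 2 and 3).

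The list of cholesterol synthesis and its regulation was called higher as well (camera, adjusted p = 2.0e-05), and not with an estimated correlation (adjusted p = 0.218 with an estimated correlation). Of 20 measured members, 5 rose and none fell, and 14 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 0.46. Fdps, farnesyl diphosphate synthase, rose by 1.07 ± 0.15 (adjusted p = 0.0205) and Msmo1, a sterol oxidase, by 0.65 ± 0.12 (adjusted p = 0.0354). The list median was 0.47, 0.37 and 0.42 on si-uc.323 replicates 1, 2 and 3. The slide-block median, 0.47, repeats the value of replicate 1. Fdps had an adjusted p of 0.109 without si-scramble replicate 1, 0.0917 without si-scramble replicate 2 and 0.131 without si-scramble replicate 3.

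In the unfolded protein response of the endoplasmic reticulum, the set of chaperones and folding enzymes induced when proteins misfold there, 9 of 19 measured members rose and none fell (11 rose adjusted over the list alone). The median log2 fold change was 0.55. Dnajb11 rose by 0.95 ± 0.12 (adjusted p = 0.0202), Pdia4 by 0.87 ± 0.14, Dnajc3 by 0.83 ± 0.14 and Canx, the lectin chaperone calnexin, by 0.74 ± 0.12. The list was called by camera (adjusted p = 0.00039, but adjusted p = 0.226 with an estimated correlation). Its medians were 0.51, 0.44 and 0.62 on si-uc.323 replicates 1, 2 and 3. The slide-block median, 0.51, repeats the value of replicate 1. Dnajb11 did not pass without si-scramble replicate 1 (adjusted p = 0.109), replicate 2 (0.0909) or replicate 3 (0.131). The integrated stress response (27 members, median log2 fold change 0.11, adjusted p = 0.751) and the cytosolic and mitochondrial chaperones (16 members, median 0.09, adjusted p = 0.62) were not called. Fgf21, a hormone in the first of these, fell by 0.68 on the log2 scale (adjusted p = 0.0267), and Trib3 did not pass (-0.50 ± 0.12, adjusted p = 0.0596; 0.0388 with normexp).

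The list of fatty acid uptake and oxidation was called lower by camera (adjusted p = 3.8e-05) and not with an estimated correlation (adjusted p = 0.106 with an estimated correlation). Of 33 measured members, 3 fell and none rose (5 fell adjusted over the list alone), 5 had a positive value, and the median log2 fold change was -0.26. Cpt1b, the muscle carnitine palmitoyltransferase that admits fatty acids to mitochondria, was lower by -0.86 ± 0.14 (adjusted p = 0.0267), and its less bright probe read -0.26. Ucp3, a mitochondrial uncoupling protein, was lower by -1.38 ± 0.20 (adjusted p = 0.0228) and Acsl1, which activates fatty acids, by -0.88 ± 0.15 (adjusted p = 0.0295). The list medians on si-uc.323 replicates 1, 2 and 3 were -0.31, -0.29 and -0.26. The slide-block median, -0.31, repeats the value of replicate 1. For Cpt1b the adjusted p was 0.125, 0.0934 and 0.145 without si-scramble replicates 1, 2 and 3, and 0.208 with the slide as a block (log2 fold change -0.70).

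The PPAR and PGC-1 regulators of oxidative metabolism were also called lower (16 members, median log2 fold change -0.09, mean -0.24, adjusted p = 0.0304; adjusted p = 0.226 with an estimated correlation). Rxrg, a retinoid X receptor, was lower by -1.43 ± 0.16 and Klf15, a transcription factor of muscle lipid metabolism, by -0.85 ± 0.13; no member rose. Ppara (-0.49 ± 0.12, adjusted p = 0.0574; 0.0398 with normexp) and Ppargc1a (-0.06 ± 0.17, adjusted p = 0.841) did not pass. The call was lost without si-uc.323 replicate 2 (median -0.16, adjusted p = 0.0597) although the median was further from 0 there; without si-scramble replicate 2 the median was -0.06 and the call held (adjusted p = 0.0369). The slide-block median, -0.19, is the value of si-uc.323 replicate 1. In glycolysis and glucose uptake 3 of 26 members fell and none rose (5 fell adjusted over the list alone; median -0.16, adjusted p = 0.004; adjusted p = 0.226 with an estimated correlation): Eno3, the muscle enolase (-0.91 ± 0.12), Pgam2, the muscle phosphoglycerate mutase (-0.75 ± 0.12), and the lactate transporter Slc16a3 (-0.60 ± 0.12). In oxidative phosphorylation 3 of 46 members fell and none rose (median -0.14, adjusted p = 0.004; adjusted p = 0.476 with an estimated correlation), namely Cox8b (-0.64 ± 0.10), Ndufa4 (-0.47 ± 0.10) and Atp5mc1 (-0.46 ± 0.10), the last of which did not pass with normexp (-0.37, adjusted p = 0.0509). With the slide as a block both of these lists had an adjusted p of 0.0502, with medians of -0.14 and -0.12. Oxidative phosphorylation was not called under normexp (adjusted p = 0.141), quantile (0.176) or cyclic loess (0.445) normalization or on the authors' series values (0.184). The tricarboxylic acid cycle was not called (19 members, median -0.05, adjusted p = 0.62). None of the genes named here passed when si-scramble replicate 1, 2 or 3 was left out, which left 0, 13 and 0 genes called.

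The list of adult myocyte genes that are known to fall in hypertrophy was called lower by camera (adjusted p = 0.004, but adjusted p = 0.218 with an estimated correlation). It had 11 members, of which 2 passed over all features, and a median log2 fold change of -0.29. The slide-block median, -0.22, is the value of si-uc.323 replicate 1. Ckm, the muscle creatine kinase, was lower by -0.89 ± 0.10 (adjusted p = 0.0174) and Kcnip2, a subunit of the transient outward potassium channel, by -1.22 ± 0.19 (adjusted p = 0.0267). Adjusted over the list alone 5 members fell: these 2, Ckmt2, Slc2a4 and Cox6a2. Slc2a4 is also in the glycolysis list and Cox6a2 in that of oxidative phosphorylation, so the called lists overlap. Pln (-0.29) did not pass, and Atp2a2 (-0.08), Casq2 (-0.11), Myh6 (0.05), Kcnd2 (0.04) and Kcnd3 (-0.05) lay near 0. The list of hypertrophy and fetal programme genes did not pass camera (13 members, 11 positive, median 0.17, adjusted p = 0.0915, and 0.458 with an estimated correlation). Fry, which does not compare a list with other genes, passed it as higher (fry adjusted p = 0.019). Over all features 2 members were higher, Ccn2 (0.67 ± 0.10), a matrix-associated growth factor, and Tnnt1 (0.66 ± 0.12, its other probe reading 1.08), the slow skeletal troponin T. Adjusted over the list alone 4 were higher and 1 was lower. The natriuretic peptides Nppa (0.17 ± 0.11, adjusted p = 0.343) and Nppb (0.30 ± 0.11, adjusted p = 0.132), the myosins Myh7 (0.29 ± 0.11, adjusted p = 0.147) and Myh6 (0.05 ± 0.13, adjusted p = 0.833) and skeletal actin Acta1 (0.00 ± 0.16, adjusted p = 0.991) did not pass. The unadjusted 95% interval was -0.08 to 0.43 for Nppa, -0.25 to 0.35 for Myh6 and -0.38 to 0.38 for Acta1, while it lay above 0 for Nppb (0.04 to 0.56) and Myh7 (0.03 to 0.55). The groups did not overlap for Nppa, Nppb or Myh7. Nppb passed in 3 of 20 alternatives, namely quantile normalization, array weights and cyclic loess (adjusted p from 0.0241 to 0.413 over all of them), and Myh7 in none (0.0533 to 0.471). The calls of Ckm, Kcnip2, Ccn2 and Tnnt1 did not hold without si-scramble replicate 1, 2 or 3 (0, 13 and 0 genes called).

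The sarcomere list was not called (24 members, median log2 fold change 0.01, mean -0.06, adjusted p = 0.512), and 1 member fell, cardiac actin Actc1 (-0.63 ± 0.11, adjusted p = 0.0314), while Myl4 did not pass (-0.38 ± 0.11, adjusted p = 0.0774). In calcium handling and ion channels (28 members, median -0.10, adjusted p = 0.134) the T-type calcium channel gene Cacna1h fell (-0.71 ± 0.12) and Jph2, which holds the junction between the cell membrane and the calcium store, lay just under the threshold (-0.71 ± 0.16, adjusted p = 0.0499995) and did not pass with normexp (-0.55, adjusted p = 0.0513). The PRC2 polycomb complex, which methylates histone H3, was not called (8 members, median 0.47, adjusted p = 0.223), although its methyltransferase Ezh2 rose by 0.88 ± 0.14 (adjusted p = 0.0267) and Mtf2 by 0.60 ± 0.13 (adjusted p = 0.0448; 0.136 with normexp). Adjusted over the list alone, 5 of its members rose and 2 fell. The list of mTOR, insulin and IGF signalling had no changed member (31 members, median 0.12, adjusted p = 0.62), and Mtor did not pass (0.39 ± 0.18, adjusted p = 0.213). Hypertrophic signalling and transcription factors had 1 member higher and 1 lower, the latter being Mef2a (-0.59 ± 0.12; 29 members, median -0.07, adjusted p = 0.62). Each of these single-gene calls was lost without si-scramble replicate 1, 2 or 3 (0, 13 and 0 genes called). Of 20 alternatives, Mtf2 passed in 6, Actc1 in 8, Jph2 in 9, Mef2a in 11, Cacna1h in 12 and Ezh2 in 13. Myl4, which did not pass as reported, passed in 2. For Ezh2 the adjusted p was 0.123, 0.0972 and 0.145 without si-scramble replicates 1, 2 and 3.

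Extracellular matrix and TGF-beta targets narrowly missed the threshold (29 members, median log2 fold change 0.20, adjusted p = 0.0537; adjusted p = 0.584 with an estimated correlation), with 6 members higher, Ccn2 among them, and 1 lower. The p53 targets were not called (17 members, median -0.04, mean 0.16, adjusted p = 0.705), but 4 members rose, among them the pro-apoptotic Pmaip1 (1.42 ± 0.19), well above background on 1 si-scramble array, and Bax (0.76 ± 0.14). Adjusted over the list alone, 4 p53 targets rose and 3 fell. Among apoptosis regulators (22 members, median 0.07, adjusted p = 0.72) 3 rose, including the death receptor Fas (0.71 ± 0.14), whose other probe read 0.13. In the inflammatory list (24 members, median -0.16, adjusted p = 0.279) 3 fell, including the chemokines Ccl2 (-0.84 ± 0.14) and Cxcl2 (-0.96 ± 0.18). In the interferon response (35 members, median -0.07, adjusted p = 0.72) Cxcl10 fell (-0.73 ± 0.15) and Irf1 did not pass (-0.49 ± 0.16, adjusted p = 0.105), its other probe reading 0.29. Nr4a2 fell among the immediate early genes (-0.77 ± 0.13, its other probe reading -0.05; 23 members, median -0.04, adjusted p = 0.318), where Jund did not pass (-0.54 ± 0.14, adjusted p = 0.0667; 0.0467 with normexp). In autophagy and lysosome (26 members, median 0.14, adjusted p = 0.85) Becn1 rose (0.79 ± 0.17) and Pink1 fell (-0.54 ± 0.10). With normexp Pmaip1 read 0.19 (adjusted p = 0.264), Fas 0.09 (0.709) and Cxcl2 -0.46 (0.0853), so that none of these passed. The single-gene calls of these lists too were absent without si-scramble replicate 1, 2 or 3 (0, 13 and 0 genes called).

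The remaining lists of cell function were not called. They were muscle atrophy ligases and FoxO targets (11 members, median 0.03, adjusted p = 0.842), where Klf15 was the 1 member that fell and Fbxo32 did not pass (-0.50 ± 0.14, adjusted p = 0.0713), NRF2 antioxidant genes (23 members, median -0.07, adjusted p = 0.62), microRNA and RNA silencing machinery (7 members, median -0.07, adjusted p = 0.729), and cytosolic ribosomal proteins (68 members, median 0.02, adjusted p = 0.873). Tnrc6b fell in the third of these (-0.60 ± 0.11; -0.38 and -0.43 on its other probes) and Tarbp2 did not pass (0.42 ± 0.14, adjusted p = 0.111). Rpl15 fell among the ribosomal proteins (-0.96 ± 0.16) and Rpl5 did not pass (0.45 ± 0.14, adjusted p = 0.102). Neither Tnrc6b nor Rpl15 passed without si-scramble replicate 1, 2 or 3 (0, 13 and 0 genes called). Of 20 alternatives, Fbxo32 passed in 4, Rpl5 in 2 and Tarbp2 in 1.

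Markers of other cell types that a ventricular culture can hold were not called as lists. The medians were 0.13 for fibroblasts (18 members, adjusted p = 0.332), 0.11 for endothelium (14 members, adjusted p = 0.705), 0.12 for smooth muscle and pericytes (14 members, adjusted p = 0.62), -0.04 for macrophages and leukocytes (18 members, adjusted p = 0.512), -0.29 for erythroid cells (7 members, adjusted p = 0.0915), 0.11 for Schwann and neural cells (11 members, adjusted p = 0.751), 0.04 for epicardium and mesothelium (9 members, adjusted p = 0.62) and -0.09 for atrial and conduction myocytes (9 members, adjusted p = 0.848). Of the fibroblast markers 3 rose, among them Postn (0.69 ± 0.12) and Fap (0.67 ± 0.13), and none fell. Adjusted over that list alone, 4 rose and 1 fell. The macrophage marker Cx3cr1 fell, as above, while Cd68 did not pass (-0.41 ± 0.11, adjusted p = 0.0654). Hbb fell (-0.61 ± 0.13) and Slc4a1 did not pass (-0.55 ± 0.14, adjusted p = 0.068). The neural list held 1 gene that rose, Stmn2 (0.81 ± 0.11), and 1 that fell, Dbh (-0.71 ± 0.11). Fap (0.34, adjusted p = 0.113) and Stmn2 (0.38, adjusted p = 0.0708) did not pass with normexp. Without si-scramble replicate 1, 2 or 3 none of these passed (0, 13 and 0 genes called). Slc4a1 passed in 5 of 20 alternatives and Cd68 in 3.

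**Figure D2:**
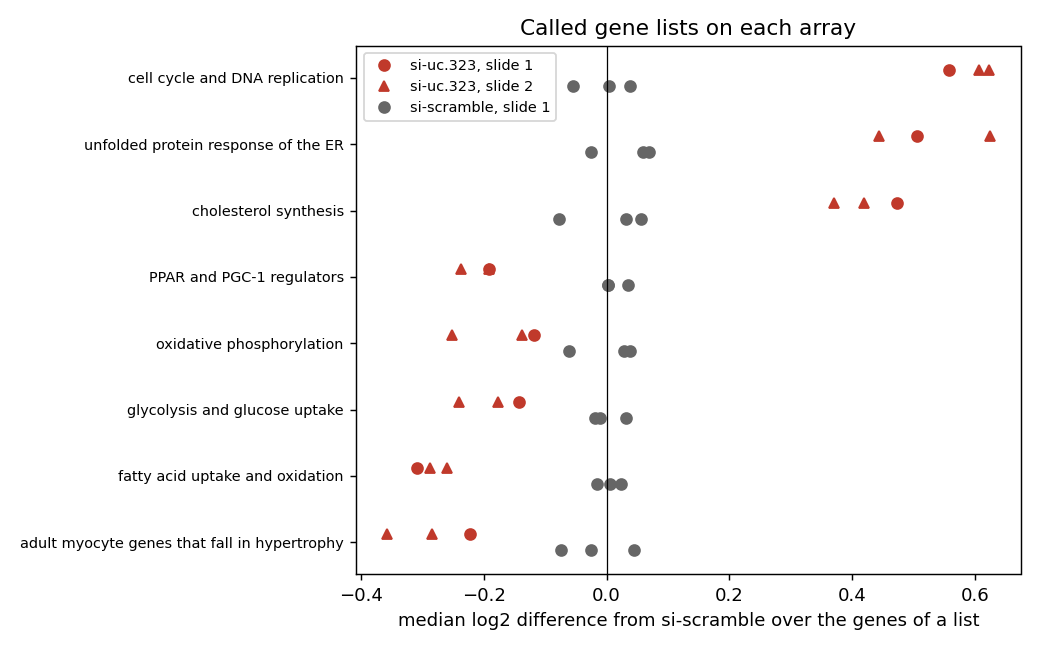
Median log2 difference over the genes of each of the 8 called lists (x axis) on each array: si-uc.323 arrays against the mean of the si-scramble arrays (red), and each si-scramble array against the mean of the other two (grey); circles are arrays of slide 1 and triangles of slide 2. The cell cycle list lay between 0.56 and 0.62 on the si-uc.323 arrays and between -0.05 and 0.04 on the si-scramble arrays, and in each of the 8 lists every si-uc.323 array lay beyond all si-scramble arrays.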

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

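Cyclic loess normalization and the fit of slide 1 alone were chosen after the data were seen, and the others before. The count of 711 genes was 1088 with quantile normalization, 1172 with a trended and robust prior, 3399 with array weights, 1240 with cyclic loess, 404 with the replicate block, 3 with the slide as a block, 25 on slide 1 alone and 0 without the background filter (limma, 3110 genes at an unadjusted p under 0.05). It ranged from 0 to 1791 when single arrays were left out, and 3481 genes had an unadjusted p under 0.05. The count of 135 genes at 2-fold was 40 with normexp, 3 with the slide as a block, 25 on slide 1 alone and 0 without the background filter, and ranged from 0 to 213 over left-out arrays. Without the filter more features were tested (27493), yet fewer genes had an unadjusted p under 0.05 (limma, 3110 against 3481). The larger number of tests alone therefore does not account for the loss. The contrast of both slide fits rests on si-uc.323 replicate 1 alone, and in the fit of slide 1 that array was assumed to vary like the controls. For the other settings, and for the lower number without the filter, the cause was not tested. Of the 8 called lists, none was called with an estimated correlation (0). Fry, which does not compare a list with other genes, passed 15 of all 36 lists, those 8 among them. It also passed hypertrophy and fetal programme genes, the PRC2 complex, p53 targets and extracellular matrix as higher. Calcium handling, inflammatory and immediate early genes passed it as lower. The cell cycle, cholesterol, unfolded protein response, fatty acid oxidation and adult myocyte lists were called under all 20 alternatives that refit camera. No called list changed direction under them.

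Same-numbered samples deviated together with correlations of 0.205, 0.39 and -0.116, and 3 of the 6 samples correlated best with their own number. The numbers were not taken as pairs, because the titles do not say that they mark a shared culture. That choice was fixed beforehand and did not rest on these correlations. The replicate block left 404 genes called, of which 357 were among the 711. Reversals concerned genes with values near 0 or near background. With normexp, Lilrb2 read -0.044, Vom2r76 -0.114 and Acta1 -0.0325. Acta1 read -0.0218 with quantile normalization, -0.101 with the median shift, -0.0287 on the series values, -0.0168 with array weights, -0.0455 with the slide as a block, -0.0455 on slide 1 alone and -0.00924 with cyclic loess. Myh6 read -0.056 with the median shift, -0.0527 with array weights, -0.0515 with the slide as a block and -0.0515 on slide 1 alone. Over left-out arrays Acta1 ranged from -0.15 to 0.13, Myh6 from -0.035 to 0.101 and Ppargc1a from -0.22 to 0.11. The cause was not tested.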

Other observations

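All tests in this part except those of the other splits and of the share of non-myocyte cells were chosen after the result was seen. Among 175 families of genes that share the root of their symbol, a grouping made after the data were seen, 4 passed camera at its preset correlation, and none of the 4 with an estimated correlation (adjusted p = 0.913 for each). The root Psm, mostly proteasome subunits (45 genes), had a median log2 fold change of 0.22 with 37 positive values (adjusted p = 0.0379 at the preset correlation), and Psmd7 (1.17 ± 0.16, adjusted p = 0.0202) and Psmd13 (1.13 ± 0.18, adjusted p = 0.0269) rose. The root Rad, mostly DNA repair genes, had a median of 0.41 (14 genes, adjusted p = 0.0379). The root Mcm had a median of 0.44 (8 genes, adjusted p = 0.0441); it holds subunits of the replicative helicase, of which Mcm6 rose (1.09 ± 0.20), and also Mcm8, Mcm3ap and Mcm10, which are not subunits of it and of which Mcm10 rose (1.20 ± 0.19). Mcm2, Mcm3, Mcm4, Mcm6 and Mcm7 are also members of the cell cycle list, so the Mcm result is in part the same observation. The root Tex had a median of -0.24 (11 genes, adjusted p = 0.0441). The direction of the 4 medians held under 6 scalings, with ranges of 0.11 to 0.26 for Psm, 0.26 to 0.41 for Rad, 0.34 to 0.44 for Mcm and -0.37 to -0.24 for Tex. These genes were picked after their values were seen, and no gene passed without si-scramble replicate 1 or replicate 3 (0 genes in each fit by limma, 2348 and 2098 at an unadjusted p under 0.05).

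Expression differed between si-uc.323 and si-scramble in 711 genes, and the highest count in the other splits of the 6 arrays was 5; 1 of the 10 splits, the real one, gave as many, and 10 splits are too few to give a share under 0.05. Markers of fibroblasts, endothelium, smooth muscle and macrophages had medians of 0.13, 0.11, 0.12 and -0.04, a range of 0.176. A changed share of non-myocyte cells, by the prediction written beforehand, would move all 4 one way and the sarcomere list the other. Without such a change, the prediction said, the 4 medians would not share a sign or would differ by more than their spread. The macrophage median had the opposite sign, which meets the first of these conditions, and the sarcomere median was 0.01. But the 95% intervals of the 4 overlapped and those of the macrophage (-0.23 to 0.12) and sarcomere lists (-0.25 to 0.11) spanned 0, so the sign difference was within the spread. The sign condition was therefore not taken as decisive, a departure from the prediction, and the explanation stays open. For the slide, the 300 genes most raised on the si-uc.323 arrays of slide 2 against 2 controls were read in si-uc.323 replicate 1 against the left-out control on slide 1. Their medians were 0.634, 0.336 and 0.722, and those of the 300 genes most lowered were -0.724, -0.658 and -0.737. Between controls the medians of raised genes ran from -0.195 to 0.179 and those of lowered genes from -0.0526 to 0.0786. The genes read between controls were chosen against 1 control instead of 2, so the comparison is not like for like. These values rest on 1 si-uc.323 array, so slide and siRNA cannot be told apart for the other arrays.

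The higher values of the cell cycle list may reflect more cells in the cycle, more of the cells that divide, or a technical difference. A rise of non-myocyte cells, which preplating and bromodeoxyuridine reduce, stays open: the highest upper 95% bound among the medians of the fibroblast, endothelial, smooth muscle and macrophage lists was 0.468 (resampling genes), above the lower bound of 0.409 for the cell cycle list. The fibroblast median was 0.13 with 12 of 18 markers positive, against a cell cycle median of 0.55. Over all features 3 fibroblast markers rose and none fell, among them Postn (0.69) and Fap (0.67, but 0.34 with normexp). Adjusted over the list alone 4 rose and 1 fell. Differences of the medians, computed only after that test had not decided (at least 0.416, lowest 95% bound 0.06), were not used to settle it. After cyclic loess normalization the median was 0.545, against a signal-dependent difference between arrays as the whole cause. In the si-uc.323 array on the slide of the controls it was 0.558, against at most 0.054 in a control, but as 1 array this leaves the slide open.

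For the cholesterol synthesis list, a candidate explanation is a wider lipid synthesis response. A list of 16 measured fatty acid synthesis genes, from which Scd and Fads1 were left out because their values had been seen, was not called (camera adjusted p = 0.833, a single list being tested, median log2 fold change 0.01, 95% interval -0.18 to 0.38). That interval, and the omission of called genes, leave the question open. A difference of the 2 list medians, computed only after that test had not decided (0.449, 95% interval 0.0293 to 0.742), was not used to settle it.

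Of 8340 unnamed probes tested, 411 passed, 257 higher and 154 lower in si-uc.323. The probe A_44_P255424 (log2 fold change 2.26 ± 0.17) and A_44_P135730 (1.28 ± 0.11) had the smallest p among those higher, and A_64_P083805 (-2.59 ± 0.22) and A_64_P051139 (-1.81 ± 0.18) among those lower.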
